A study of Arabidopsis thaliana with 4 samples.

How the data were processed

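Gene expression was measured in whole seedlings of Arabidopsis thaliana, ecotype Columbia, with 4 Affymetrix one-colour arrays. Per the labels, seedlings grew for 15 days after germination, 2 arrays are controls and 2 come from seedlings treated with GSH (reduced glutathione, the tripeptide thiol of plant cells) for 72 hours. Total RNA was extracted with Trizol and biotin-labelled cRNA was made from 6 µg of it, per the labels' protocols. The dose of GSH is not given in the sources used here, and neither is whether control seedlings were kept for a further 72 hours, so age at harvest may differ between the groups. Each array's group and replicate number came from its title. The free-text description of the samples and part of the design text speak of embryos, which the source, tissue and age labels contradict, and neither was used.

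The deposited values are log2 expression values, 1 per probe set and array, made with Affymetrix Expression Console and RMA (background correction, quantile normalization and median polish of the probes of a probe set), per the submitters' processing notes, which give no versions. The values of the 22810 probe sets were used as deposited. Quantile normalization gives every array nearly the same distribution, so a change shared by most transcripts would not be visible, and differences of very bright or very dim probe sets are compressed. No detection calls were used, so low values are not shown to be above background and differences that involve them are of uncertain size. Among the genes called and named these are BGLU27, AT1G09310, GSTU25 and THI2.1. Little above them lie GH3.3, AT1G09500, AT5G02540, TUB1 and TUB5 in 1 group and DTX3 in both. Precision is limited by the number of arrays. The 64 control probe sets were left out of the tests on genes.

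Probe sets were named through the platform annotation, which is old, and updated by gene identifier to RefSeq symbols of assembly TAIR10.1. Of the 22746 probe sets tested, 13513 carried 1 gene, 503 several and 8730 none in that table. Of those with 1 gene, 13436 matched a RefSeq gene and 77 kept the annotation's symbol, and they stand for 13356 genes. Probe sets with several genes or none were tested but not named. No coordinates are given, since no genome build is named for the array. Chloroplast-encoded genes were those RefSeq places on the plastid chromosome and mitochondria-encoded genes those whose annotation symbol equals a RefSeq mitochondrial symbol, because the tables hold other locus codes than the plastid and mitochondrial codes planned.

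Treated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the single factor, 2 residual degrees of freedom per probe set and a prior of 4.55), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A second count took probe sets at least 2-fold apart whose treated values both lie on the same side of both control values. Errors of log2 differences are moderated standard errors from limma with 2 arrays per group. The titles call the replicates biological, but no label says that they came from separate cultures, so p-values measure only the spread between these arrays.

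Before the data were examined, 30 lists of genes with 563 entries (554 distinct genes) were fixed, together with the chloroplast-encoded and mitochondria-encoded genes, the rule for naming genes, the tests and the alternatives. Of those 554 genes, 82 had a probe set with 1 named gene. A list member was taken at its probe set with the highest mean over the 4 arrays, and 18 lists held 3 or more measured genes. These were tested against all other genes with limma's camera (two-sided, preset correlation 0.01). The alternative with an estimated correlation takes its p-values from the 2 residual degrees of freedom, so it has little power with 4 arrays. For 71 of the 82 genes the RefSeq symbol or a synonym matched the list, 9 carried a locus code alone, 2 carried another name of the same gene, and no member was left out. No member was measured in the lists on ethylene, antioxidant enzymes, indole glucosinolates and camalexin, nitrate and ammonium, ferritins, morning clock genes, flowering and seed storage, so the flowering and seed markers give no information here.

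The genes named are, among probe sets with 1 gene, the 12 with the largest increase and the 12 with the largest decrease past the threshold with no overlap between the groups. In each list described, up to 4 members with the smallest unadjusted p were named, and up to 8 in the lists on glutathione, sulfur and salicylic acid. Other genes named were chosen after their values were seen, and the text says so.

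Data were simulated with the real control means, spreads drawn from limma's fitted prior, and independent probe sets. There limma recovered 14 of 50 probe sets changed by 0.5 log2 units (28%) and 50 of 50 at each of 1, 2 and 3 log2 units. It called 11 of 22546 unchanged ones, over 22746 probe sets. Over 13356 simulated genes, camera called the 1 list shifted by -0.5 and 0 of 17 unshifted lists. Far fewer probe sets were changed than passed in the real data, so these recovery rates do not carry over to them. With independent genes, the simulation does not check the preset correlation. The alternatives were the replicate number as a block, an intensity trend with a robust prior, centring on array medians, quantile normalization of the deposited values, removal of the lowest 25% by mean log2 value (under 4.06), removal of probe sets with the suffix _s_at or _x_at, unmoderated statistics, leaving out each array, other fold thresholds, and for lists an estimated correlation, fry, and the mean of a gene's probe sets.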

Results

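Expression was measured on 4 arrays, 2 from control seedlings and 2 from seedlings given GSH for 72 hours. Median log2 values were 5.38 and 5.36 on the control arrays and 5.34 on both treated arrays, after the authors' quantile normalization. The 2 control arrays correlated at r = 0.998 across genes and so did the 2 treated arrays, while pairs across the groups correlated at 0.982, values that describe the arrays because genes are not independent replicates.

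The series asks how GSH affects the expression profile of Arabidopsis. Treated seedlings held more transcript of the auxin-inducible GH3.3, of the beta-glucosidase genes BGLU45 and BGLU27 and of the chaperone genes ERDJ3B and CRT1B. Signals on the treated arrays were lower for 46 of the 69 genes measured from the chloroplast, beside a lower signal for 25S ribosomal RNA (-2.97 ± 0.09 log2 units). For the chloroplast genes, a response to GSH cannot be told apart from an unequal loss of RNA without poly(A) tails. GH3.3, which conjugates auxin to amino acids, was 10.5-fold higher (log2 difference 3.39 ± 0.14, SE, n = 2 per group), a size that is uncertain because its control mean of 4.28 was not shown to be above background. The chloroplast gene psbD, for a core protein of photosystem II, was 9.68-fold lower (log2 difference -3.28 ± 0.07, SE, n = 2 per group). Of 22746 probe sets, 7680 (33.8%) differed at an adjusted p under 0.05 with limma, 3692 higher and 3988 lower in treated seedlings. That balance turned to 4043 higher and 3729 lower when each array was centred on its median. Most of the 7680 differences were small, with a median size of 0.48 log2 units, and 63.5% were under 1.5-fold. Control probe sets for spiked-in RNA, which does not come from the seedlings, also passed. For Bacillus RNA 11 of 27 did and for hybridization controls 4 of 18, all lower. The count of 7680 thus does not separate technical differences from a response to GSH. At least 2-fold differences without overlap between the groups were found for 900 probe sets (3.96%), 516 higher and 384 lower, all of them past the limma threshold. Groups did not overlap for 65.2% of probe sets at any size, against 33.3% that chance gives for 2 arrays against 2. Without moderation of the spread 1425 probe sets passed in place of 7680, so the number called rests on the variance shared across probe sets by limma.

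Among the 12 largest increases, AT5G12340 rose by 3.46 ± 0.08 log2 units (limma adjusted p = 5.15e-06), from 6.48 to 9.94 in log2 value. The beta-glucosidases BGLU45 and BGLU27 rose by 3.12 ± 0.08 and 2.90 ± 0.12 log2 units, where the control mean of BGLU27 (4.01) lay among the lowest 25% of values and was not shown to be above background, so the size of its difference is uncertain. AT3G53600, a C2H2 zinc finger gene, rose by 3.22 ± 0.09 and AT1G09500 by 2.93 ± 0.07. AT5G52810, whose enzyme acts in the synthesis of the immune signal pipecolic acid, rose by 2.53 ± 0.09. GFAT, for the first enzyme of hexosamine synthesis, rose by 2.35 ± 0.08, and TAAC, named as a thylakoid carrier of ATP and ADP, was 4.93-fold higher. AT2G15780, AT2G19970 and AT3G60420 rose by 2.69, 2.66 and 2.36 log2 units. All 12 had limma adjusted p-values of 2.28e-05 or less.

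Among the 12 largest decreases, LCR69, a small cysteine-rich peptide of the defensin type, fell by 3.40 ± 0.24 log2 units (limma adjusted p = 0.000132), and its treated arrays differed more from each other than those of the other genes named here, at 6.35 and 5.52. Chloroplast genes took 4 places, with psbD at the values above, psbB of photosystem II at -2.59 ± 0.07, atpF of the ATP synthase at -2.44 ± 0.09 and petL of the cytochrome b6f complex at -2.19 ± 0.08. AT5G11420 and AT3G08030, which belong to the DUF642 family of cell wall proteins, fell (-2.66 ± 0.09 and -2.62 ± 0.09). AT1G09310, AT2G10940 and AT5G02540 fell as well (-3.20, -2.84 and -2.77), as did AT2G24600 (-2.21) and AT5G16030 (-2.18), and the treated mean of AT1G09310 (3.99) lay equally low, so the size of its difference is uncertain too. Probe sets without a gene in the tables reached further, up to 4.64 ± 0.09 and down to -3.70 ± 0.08.

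**Figure D1:**
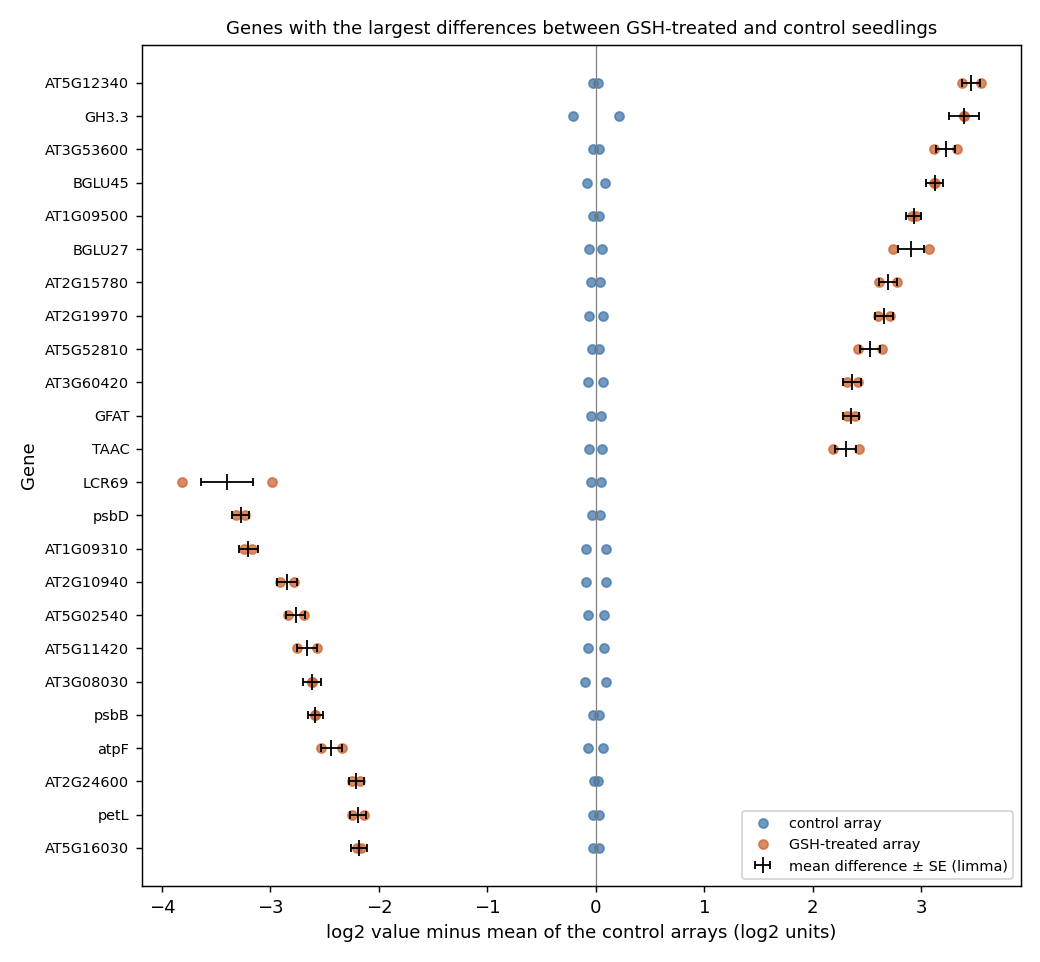
Log2 values of the 24 genes with the largest differences, drawn relative to the mean of the control arrays (horizontal axis, log2 units). Blue points are the 2 control arrays, orange points the 2 GSH-treated arrays, and black bars the mean difference with its standard error from limma. Mean differences run from -3.40 for LCR69 to 3.46 for AT5G12340.

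Chloroplast-encoded transcripts gave lower signals on the treated arrays, which a response of the seedlings or an unequal loss of RNA could both give. Of 69 measured genes, 46 fell, 2 rose and 21 did not pass, and 54 passed when adjusted over the list alone. The median log2 difference was -0.60 (mean -0.83), and camera put the list below other genes (limma adjusted p = 2.87e-19, but adjusted p = 0.403 with an estimated correlation). Photosystem II genes spread from -3.28 for psbD to -0.03 for psbM, with 11 of 15 lower. In photosystem I, 4 of 5 fell, in the ATP synthase 5 of 6, in the cytochrome b6f complex 4 of 6 and in the NDH complex 6 of 10. Of the 4 genes for the plastid's own RNA polymerase 3 fell, and of 15 for ribosomal proteins 8 fell while rps18 (0.37) and rpl33 (0.25) rose. The transcript of rbcL, the large subunit of Rubisco, differed by -0.06 and did not pass, and psbM, rps18, rpl33 and rbcL were named after their values were seen. Beside this group, the control probe set for 25S ribosomal RNA was also lower, at a mean log2 value of 11.06 on the control arrays against 8.09 on the treated arrays (-2.97 ± 0.09, SE), while the dim probe set for 5S ribosomal RNA stood at 0.11 and did not pass. The difference between 3' and 5' signals of actin, GAPDH and ubiquitin control genes changed little between the groups. Treated minus control, it moved by -0.11 to 0.12 log2 units in 6 pairs. The difference itself was large in some pairs, such as 3.80 for an actin pair on control replicate 1.

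**Figure D2:**
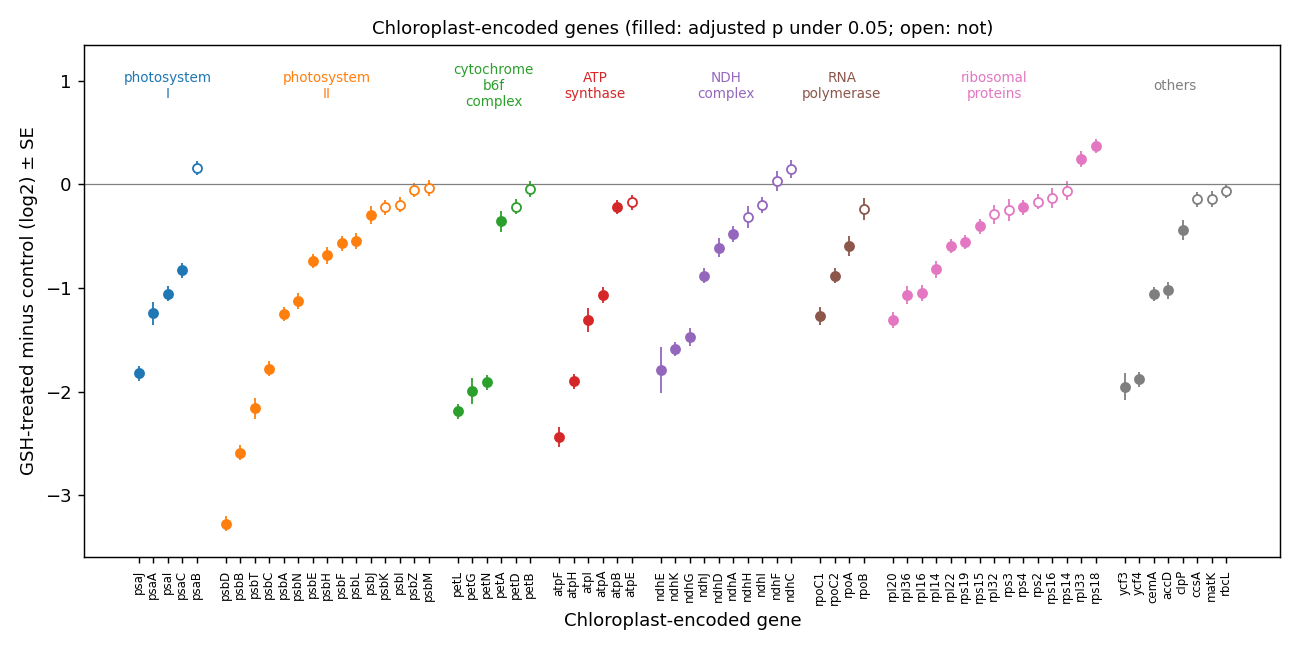
GSH-treated minus control log2 difference (vertical axis) with its standard error for each of the 69 chloroplast-encoded genes, grouped by the complex they belong to. Filled points passed limma's adjusted p of 0.05 and open points did not. Values run from -3.28 for psbD to 0.37 for rps18.

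Mitochondria-encoded transcripts were lower too. Of 11 genes 6 fell, 0 rose and 5 did not pass, and 7 passed when adjusted over the list alone. The subunits cox1 and nad4 of the respiratory chain fell by 1.06 ± 0.07 and 0.77 ± 0.08 log2 units, nad5 fell by 0.62 and nad2 by 0.76. The median was -0.25, and the list lay below other genes by camera (limma adjusted p = 0.0278, against adjusted p = 0.403 with an estimated correlation). The lower 25S ribosomal RNA signal given above stands beside this group too, and the 27 control probe sets for spiked-in Bacillus RNA, which carries poly(A) tails, had a median of -0.26. Without control replicate 1 the camera adjusted p from limma was 0.0678.

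The 6 measured nuclear photosynthesis genes had a median of -0.21. The antenna protein gene LHCB4.2 fell by 0.42 ± 0.07 and RCA, for Rubisco activase, by 0.24 ± 0.07, while LHCB4.3 (-0.22) and LHCB4.1 (-0.21) did not pass, 2 of 6 in all and also 2 when adjusted over the list alone. Camera did not call this list (limma adjusted p = 0.12). Among root markers, PYK10 (-0.25), EXPA7 (-0.20) and EXPA18 (0.13) did not pass over all probe sets or adjusted over the list alone (0 of 3), and their group means lay between 3.94 and 4.33.

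Most of the few measured genes for protein folding and heat shock were higher. They were 3 of 15 members of the endoplasmic reticulum list and 4 of 15 of the heat shock list. In the list on the endoplasmic reticulum, the chaperone genes ERDJ3B and CRT1B rose by 1.67 ± 0.07 and 1.36 ± 0.07 log2 units, while the transcription factor gene BZIP60 stood at 0.00 (2 of 3 past the threshold, also 2 adjusted over the list alone). Of 4 heat shock genes 3 rose, the small heat shock protein genes HSP17.6C by 1.47 ± 0.08 and HSP17.6B by 0.97 ± 0.08 and HSA32 by 0.41 ± 0.07. HSP22 (0.34) lay in the lowest 25% of log2 values and passed only when adjusted over the list alone, where 4 passed. Camera called both lists higher (limma adjusted p = 0.0278 and 0.00716, and adjusted p = 0.403 for both with an estimated correlation). Without treated replicate 1 the adjusted p for the endoplasmic reticulum list was 0.0505 by limma's camera, and with the lowest 25% of probe sets removed it was 0.0508, as it was for the mitochondria-encoded genes.

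The measured genes of the detoxification list on xenobiotics and electrophiles rose. They were 5 of its 19 members, and all 5 passed over all probe sets and adjusted over the list alone. In the separate list on glutathione S-transferases 11 of 13 did not pass. DTX4, of a family of efflux carriers, rose by 0.57 ± 0.08 log2 units, the alkenal reductase gene AER by 0.51 ± 0.08, DTX3 by 0.28 ± 0.07 and the glucosyltransferase gene UGT73B5 by 0.48 ± 0.14. Camera called the list higher (limma adjusted p = 0.0174, with adjusted p = 0.403 with an estimated correlation). No list passed with an estimated correlation, under which the smallest adjusted p over the 18 lists was 0.403. That setting rests on 2 residual degrees of freedom and has little power to call any list. For the mitochondria-encoded genes the unadjusted camera p went from 0.00772 to 0.108, though their estimated correlation of -0.0322 lay below the preset 0.01. The loss of that call therefore cannot be put down to correlation among genes. For the chloroplast, heat shock, endoplasmic reticulum and detoxification lists the estimated correlations were 0.198, 0.406, 0.215 and 0.15, above the preset. In those lists correlation among genes and low power cannot be told apart. By contrast fry called 14 of the 18, but fry asks whether members move one way on balance and compares a list with no other genes.

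Most genes of the glutathione and sulfur lists were not measured. The measured ones were 3 of 22 for glutathione, 3 of 26 for sulfate and 2 of 12 for sulfur starvation. They changed singly, and the pathways as wholes were not covered. GGCT2;3, of the family that breaks glutathione down in the cytosol, rose by 0.92 ± 0.11 log2 units and the glutathione reductase gene GR1 by 0.30 ± 0.08. GR2, for the organellar glutathione reductase, stood at -0.17 ± 0.07 and passed only when adjusted over the list alone, where 3 of 3 passed against 2 of 3 over all probe sets (camera by limma, adjusted p = 0.325). Among 13 glutathione S-transferase genes, GSTU28 (0.60 ± 0.14) and GSTU25 (0.43 ± 0.14) rose and 11 did not pass, and 0 passed adjusted over the list alone (limma adjusted p = 0.423 by camera). Of these 13, 7 lay in the lowest 25% of log2 values. APS3, for an ATP sulfurylase that activates sulfate, rose by 1.53 ± 0.09, while APS4 (-0.05) and the sulfite reductase gene SIR (-0.11) did not pass, 1 of 3 also when adjusted over the list alone. The sulfate list thus had a median of -0.05 against a mean of 0.45 and a camera direction upward (limma adjusted p = 0.521). Among sulfur starvation markers SDI2 rose by 0.61 ± 0.07 and BGLU28 stood at -0.02, 1 of 2 also when adjusted over the list alone.

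Defence and hormone lists went both ways. In the salicylic acid list GRXC9, a glutaredoxin gene, rose by 0.67 ± 0.09 log2 units and SAG101, a partner of EDS1 in immunity, fell by 0.29 ± 0.07 (2 of 2, also adjusted over the list alone). Among immunity markers WRKY53 fell by 1.60 ± 0.09 and BIK1 by 0.29 ± 0.07, while WRKY22 rose by 0.30 ± 0.07 (3 of 3, also adjusted over the list alone). Of 5 jasmonate genes, THI2.1, a thionin, fell by 1.18 ± 0.13 and OPCL1 by 0.56 ± 0.07, and 3 did not pass (2 adjusted over the list alone). Camera gave limma adjusted p = 0.132 for jasmonate, but 0.0295 without treated replicate 2. UPOX and WRKY6 of the oxidative stress list rose by 1.27 ± 0.09 and 0.64 ± 0.07 and ZAT10 stood at -0.09 (2 of 3, also adjusted over the list alone). In the auxin list GH3.3 and GH3.5 (0.52 ± 0.07) rose and 4 of 6 did not pass, with 2 past the threshold adjusted over the list alone. LTI30, a dehydrin, fell by 1.09 ± 0.07 as the single one of 4 drought and cold genes, and UGT74B1 rose by 0.97 ± 0.07 as the single one of 3 aliphatic glucosinolate genes, with 1 in each list also when adjusted over the list alone. Camera called none of these tested lists, with limma adjusted p-values of 0.325 for immunity, 0.12 for oxidative stress and for auxin, 0.204 for drought and cold and 0.48 for glucosinolates.

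The remaining lists showed little. ARR16, a cytokinin response gene, fell by 0.46 ± 0.11 log2 units and ARR15 stood at -0.14. PYE, an iron regulator, fell by 0.42 ± 0.08 and BHLH101 stood at -0.04. In the senescence list WRKY53 fell, as above, and SAG29 stood at 0.06, and each of these 3 lists had 1 of 2 past the threshold, also when adjusted over the list alone. None of 5 phenylpropanoid and flavonoid genes passed (DFR at 0.14), nor did any of 3 cell cycle genes (MCM7 at 0.13). When adjusted over the list alone 0 passed in each, with limma adjusted p = 0.893 and 0.489 by camera. Group means of the 3 cell cycle genes lay between 3.82 and 3.96 and were not shown to be above background. That these genes did not pass therefore gives no information on the cell cycle. The median of the phenylpropanoid list was 0.00 and its mean -0.01, while camera put it upward. GI, the 1 evening clock gene measured, stood at -0.05 and did not pass, also when adjusted over the list alone.

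**Figure D3:**
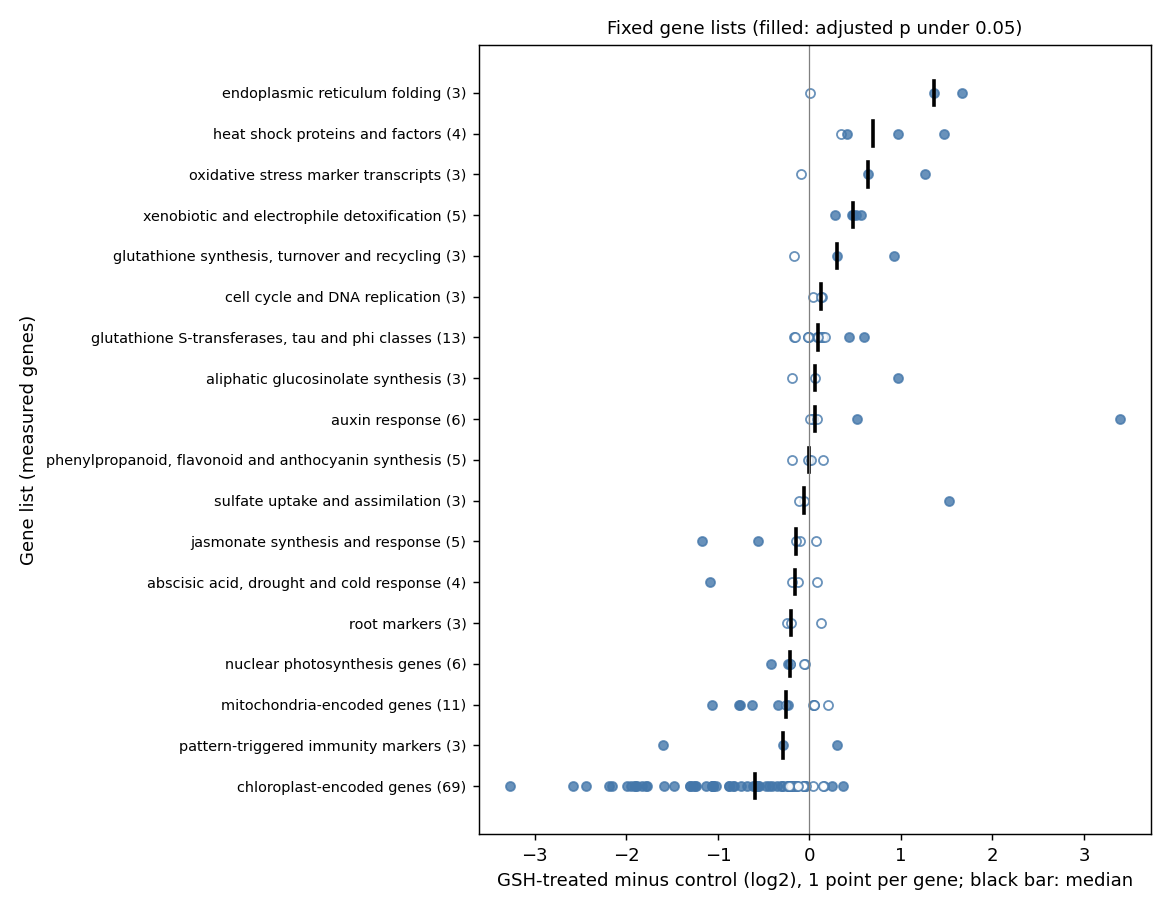
GSH-treated minus control log2 difference (horizontal axis) of each measured member of the 18 lists with 3 or more genes, with the number of genes in brackets. Filled points passed limma's adjusted p of 0.05, open points did not, and black bars are list medians, which run from -0.60 for chloroplast-encoded genes to 1.36 for endoplasmic reticulum folding.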

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

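All tests in this part were chosen after the results were seen. Among the 64 control probe sets, which enter no comparison of genes, all 5 for GAPDH lay higher on both treated arrays than on both control arrays, and 3 of them passed the threshold, at 0.29, 0.35 and 0.29 log2 units (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0313, 0.0215 and 0.0209), while the other 2 (0.17 and 0.16) did not. The 3 stayed higher with arrays centred on their medians and with quantile normalization.

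Chloroplast-encoded transcripts were lower as a group while the 25S ribosomal RNA signal was lower too, and both kinds of RNA lack stable poly(A) tails, although the dim 5S ribosomal RNA probe set was not lower (0.11). A uniform loss of such RNA from the labelled material is argued against as the whole cause by the spread of 39 chloroplast genes. These genes had mean log2 values from 6 to 11. Their interquartile range was 1.09 log2 units against a median standard error of 0.077 (1.02 over 34 genes chosen by their control mean). That standard error covers spread between arrays, not differences in how probe sets respond. A uniform loss beside other differences between the genes stays open. A smaller share of green tissue is argued against as the whole cause in the same way: 18 genes of the photosystems, the cytochrome b6f complex and the ATP synthase in that range had an interquartile range of 1.06 against a median standard error of 0.076, and a smaller contribution stays open (6 nuclear photosynthesis genes had a median 0.38 above that of the 69 chloroplast genes, permutation p = 0.29, and p = 0.033 in an exact rank-sum test run second). An unequal loss cannot be told apart from a response of the chloroplast to GSH, which the design does not separate from RNA handling. Mitochondria-encoded genes were lower too (median -0.25), but so were the spike-in RNAs that carry poly(A) tails (median -0.26), so a shift of that size is not specific to RNA without tails.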

How the results depend on the processing

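The crossed replicate block was chosen after the data had been seen, and all other alternatives before. Deviations of same-numbered arrays from their group means were only weakly related (r = -0.103 across genes), so the values show no strong effect shared by same-numbered arrays. Whether those samples were grown or processed together cannot be told from this. With the replicate block 6235 probe sets passed by limma in place of 7680, and with the pairing crossed 6898 did. The count stayed within 1.5 times under every other alternative except unmoderated statistics, which gave 1425, and 8 list genes in place of 33. Leaving out 1 array, which leaves a single array whose spread is taken to be that of the other group, gave 6186 to 6248 probe sets, 917 to 928 at least 2-fold apart, 23 to 29 list genes and 4 to 6 lists. A threshold of 1.5-fold gave 2807 in place of 900 and 3-fold gave 271, as a looser and a stricter threshold must. Of lists, 5 were called, 3 with the low filter, 0 with an estimated correlation and 14 by fry. The cause of the other changes was not tested. Single genes were followed under the alternatives only for the measured members of the 30 lists and the 24 genes with the largest changes. None of these genes, and none of the lists, past the threshold changed direction. Of the 49 followed genes not past it, 23 changed sign in at least 1 alternative. Other chloroplast, mitochondrial and family genes were not followed singly. The 24 genes with the largest changes kept their direction in all 264 alternative values and passed in 260, the other 4 being lost with unmoderated statistics. Dim probe sets limit what can be seen, as 7 of 13 glutathione S-transferase genes lay in the lowest 25% of values.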

Other observations

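Gene families were defined after the data had been seen, as every family of 5 or more measured genes that share the leading letters of their symbol, and all tests in this part were chosen after the results were seen. Beta-tubulin genes were lower in treated seedlings: TUB5 fell by 1.54 ± 0.17 log2 units, TUB6 by 1.51 ± 0.07, TUB1 by 0.74 ± 0.09 and TUB7 by 0.44 ± 0.08, 4 of 5 genes, with TUB9 at -0.10. The treated means of TUB5 (4.46) and TUB1 (4.40) were low, so the sizes of their differences are uncertain. Autophagy genes were higher, 5 of 8, led by ATG8H (1.38 ± 0.07), ATG8D (0.84 ± 0.07) and ATG8E (0.51 ± 0.08), which encode forms of the ubiquitin-like protein that coats autophagosomes. Of 11 genes for PRA1 proteins, which act in vesicle traffic, 7 rose, with PRA1.B4 at 0.88 ± 0.08. Aldehyde dehydrogenase genes fell in 5 of 8 cases, ALDH11A3 by 1.32 ± 0.07 and ALDH3F1 by 1.05 ± 0.08. Of 15 IQD genes, for calmodulin-binding proteins, 6 fell, IQD24 by 1.21 ± 0.09, and of 29 serine carboxypeptidase-like genes 9 fell and 0 rose. These 6 of 44 families were called by camera with limma adjusted p-values of 0.0158 to 0.0263, with the same direction under both other scalings. With an estimated correlation, which has little power here as stated for the lists, 0 were called (adjusted p = 0.651 for each).

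Beta-glucosidase genes went both ways. Of 20, 7 rose (BGLU45 and BGLU27 among them) and 2 fell, with BGLU25 at 1.41 ± 0.08 and BGLU16 at 0.65 ± 0.07 against BGLU44 at -1.18 ± 0.07, and camera did not call the family (limma adjusted p = 0.24). Among 9 xyloglucan endotransglucosylase genes, whose products remodel the cell wall, 5 fell and 1 rose, XTH16 at -1.74 ± 0.12 against XTH29 at 1.64 ± 0.08 (camera by limma, adjusted p = 0.155). Of the 27 control probe sets for Bacillus spike-in RNA, 11 were lower on the treated arrays and 0 higher (median -0.26 log2 units), of 18 for hybridization spike-ins 4 were lower and 0 higher (median -0.17), and of 17 for housekeeping genes 3 were higher and 0 lower (median 0.14).

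Photosystem genes of the chloroplast had a lower median than its genes for RNA polymerase and ribosomal proteins, -0.79 over 20 psa and psb genes against -0.40 over 19 rpo, rpl and rps genes. A candidate explanation is lower transcription by the plastid-encoded RNA polymerase, which reads most photosystem genes, but the gap of -0.38 had a two-sided permutation p = 0.17 and leaves this hypothesis unsupported. Over the 11 and 13 genes with mean log2 values of 11 or less the gap stood at -0.72 (permutation p = 0.034, unadjusted). This cannot decide whether compression of bright probe sets affects the gap. Compression shrinks the falls of bright genes, and more photosystem than other genes were left out, so it would also let the gap widen. The mean log2 value falls with the change itself. Over the 9 and 13 genes with control means of 11 or less the gap was also -0.72, with a permutation p = 0.059, so the subsets do not replace the test on all genes. Genes of one operon are transcribed together, so genes are not independent here and these p-values are too small.

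The 4 arrays can be split into 2 and 2 in 3 ways, and 1 split, the real one, called as many as 7680 probe sets by limma, while the other two called 0 each (33 and 71 at an unadjusted p under 0.05). Each of the other splits put 1 control and 1 treated array on each side. Any difference between control and treated arrays, whatever its cause, thus entered the spread, and few calls there were built in. The splits therefore do not separate a response to GSH from technical differences. With 3 splits no share under 0.05 can be reached.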
